A study of Caenorhabditis elegans with 12 samples.

How the data were processed

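Small RNA libraries were made from whole young-mother Caenorhabditis elegans that had been synchronized by starvation and raised at 20 °C on HT115 bacteria producing double-stranded RNA of 400 nt against the gene pos-1, per the labels' protocols. The strains were the wild type N2, the double mutant meg-3(ax3055) meg-4(ax3052) and the mutant rde-11(hj37). The titles of the meg-3 meg-4 replicate 2 libraries carry another strain number than those of replicate 1, and they were taken as replicates of 1 group because their genotype labels are the same. RNA from each strain went into the TruSeq small RNA kit either after treatment with 5′ polyphosphatase or without it. The kit ligates an adapter to a 5′ monophosphate, so untreated RNA yields mainly microRNAs, piRNAs and primary small interfering RNAs, whereas treated RNA also yields the secondary 22G RNAs, which carry a 5′ triphosphate and are made by RNA-dependent RNA polymerases. This gave 6 groups of 2 libraries, 12 libraries in all.

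The authors deposited 4 tables, each comparing 1 mutant with N2 for 1 RNA treatment. Per the file headers, the deposited values are fpm per library (the CPM unit, fragments scaled to the library total, with no correction for gene length), and each table also holds a log2 fold change and an adjusted p-value. The submitters' processing notes name cutadapt, Bowtie2, HTSeq, DESeq2 and the genome build ce10, without versions. Whether HTSeq counted by strand, how reads that align to several places were treated and which read lengths were kept are not given in the sources used here. Each table lists 42048 genes, of which 34246 had a read in some library, and no line lacked a gene name. The N2 values of one RNA treatment were equal in both tables that carry them. The 8 columns of authors' averages were not used.

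The fpm values were whole multiples of a step that was constant within a library, so reads could be recovered: 100% of the values above 0 came out whole at a tolerance of 0.01 reads. Libraries held 3884534 to 5278777 reads assigned to genes, so that 1 read was worth 0.189 to 0.257 fpm. A gene at 0 reads is compatible with up to 3 reads, and this floor covers counting error only, since reads without molecular identifiers are not independent molecules. Because Bowtie2 placements were turned into counts by gene, near-identical or overlapping genes can hold the same reads. Of the lines of the table, 3126 were identical to another line and held 17.9% of all fpm. Small RNAs from opposite strands of overlapping genes cannot be told apart here. Among the genes with the largest changes, those that overlap another gene are counted or named for each comparison. Other named genes are not marked for overlap.

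Gene names and gene classes came from the RefSeq and Ensembl annotations of the assembly WBcel235, which matched 41759 identifiers (99.3%) and gave 1809 current names for genes listed under older ones. That assembly is not the build of the deposited tables, so it was used for names, classes and the question of which genes neighbour or overlap each other, and no coordinates are given.

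The planned test for counts would have been edgeR; the tables hold normalized values, for which limma on a log scale was planned. Each mutant was compared with N2 within 1 RNA treatment (2 against 2 libraries) with limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(fpm + 1), for genes with a mean of at least 1 fpm over the 4 libraries. Fold changes are on this log2 scale, which understates the change of genes with few reads. Adjusted p-values are Benjamini-Hochberg values over the genes tested, and a gene was called at an adjusted p under 0.05. The difference between a mutant's changes in the treated and untreated RNA was an interaction term in limma over 8 libraries. The plan had foreseen standard errors of deposited fold changes for that term when counts were missing, but no such column was among those used, so the limma fit took its place. The mutants were compared with each other in limma over the 6 libraries of one RNA treatment. As planned for tables without counts, each gene list was tested with a two-sided Fisher's exact test of called members against all other tested genes, with Benjamini-Hochberg adjustment over the lists, and its median change was set among the medians of 10000 random lists matched on mean level. Fisher's test treats genes as independent. camera from limma was added at a preset correlation of 0.01 between genes, and then with an estimated correlation. With 2 against 2 libraries, the estimated correlation leaves camera few degrees of freedom and little power. A list that it does not call in that setting is therefore not shown to be unchanged.

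Recovered reads were also tested with the quasi-likelihood method of edgeR 4.0.16 (TMM scaling) and with DESeq2 1.42.0. The latter gave log2 fold changes within 0.000477 of the authors' deposited table in every comparison. Overlap between the mutants' calls was set beside the number for independent lists and beside the mean of 100 simulations with no effect in which both mutants shared the N2 libraries. Enrichment among called genes was judged by 10000 random draws of genes matched on mean level. The edgeR fits with TMM scaling, the edgeR interaction, the use of the deposited calls, the comparison of the mutants with each other, the centrings of the interaction, camera at the preset correlation and the list test with genes of identical reads counted once were chosen after seeing the data.

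The following were fixed before the data were examined: the grouping of samples, the main test, the 22 gene lists, the alternatives and the rule for naming genes. That rule names pos-1, meg-3, meg-4, rde-11, sid-1, hrde-1 and hrde-2 in every comparison. It then names, at a mean of at least 50 fpm, the 10 called genes with the largest rise and the 10 with the largest fall in treated RNA, 5 and 5 in untreated RNA, and up to 4 called members of each list by adjusted p. Names outside this rule were chosen after their values were seen, and the text says so where they occur.

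The tests were checked on simulated counts drawn from the means and depths of the real libraries, with 200 genes changed. Within a comparison all genes had a common dispersion (spread between libraries), which real genes do not share. The changed genes had a mean of at least 10 fpm in N2, in both RNA treatments for the interaction. The recovery rates hold for such genes, and lower levels were not checked. With limma, the share of 4-fold changes recovered was 98.5% for meg-3 meg-4 and 100% for rde-11 in treated RNA (16403 and 16515 genes), and 100% for both in untreated RNA (11022 and 11060 genes). For 2-fold changes it was 37.3% and 86.6% in treated RNA and 71.6% and 68.7% in untreated RNA. Of the limma calls in these simulations, 5.42% for meg-3 meg-4 and 6.37% for rde-11 were false in treated RNA, both above the nominal level, and 3.21% and 2.72% in untreated RNA. The interaction fit recovered 37.3% of 4-fold and 89.4% of 8-fold differences for meg-3 meg-4 (16730 genes), and 77.6% and 97.0% for rde-11 (16659 genes).

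Alternatives changed the tool, the scaling (DESeq2 size factors, or centring on the median gene at a level of 50 fpm or on the median microRNA), the filter on low values, the pseudocount (0.5 and 5), the threshold, the libraries in the fit, the replicate number as a block and each library in turn. Replicates of a group differed by more than sampling noise in every group, with a chi-square per gene between 3.76 and 14.5 (the highest in treated RNA of meg-3 meg-4), so no library was counted as a repeat of another. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.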

Results

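Small RNAs of whole young-mother Caenorhabditis elegans fed bacteria that make double-stranded RNA against pos-1 were sequenced in the wild type N2, in the double mutant meg-3 meg-4 and in the mutant rde-11. pos-1 encodes a maternally supplied zinc finger protein needed for embryonic cell fates. MEG-3 and MEG-4 are intrinsically disordered proteins of P granules, the RNA-rich condensates of the germline, and RDE-11 is a zinc finger protein needed for the amplification of exogenous RNA interference, in which RNA-dependent RNA polymerases make secondary small RNAs from the targeted transcript. The series asked how meg-3 and meg-4 bear on that amplification. RNA was either treated with 5′ polyphosphatase, so that secondary small RNAs with a 5′ triphosphate enter the library too (treated RNA below), or left untreated, so that mainly small RNAs with a 5′ monophosphate do. Each of the 6 groups had 2 libraries, with 3884534 to 5278777 reads assigned to genes per library.

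The make-up of the libraries differed between RNA treatments by far more than the spread between replicates. In treated RNA of N2, protein-coding genes held 60.5% ± 2.04 of the reads, microRNAs 19.399% ± 1.76 and piRNAs 6.90% ± 0.0550 (mean ± SD, n = 2). In untreated RNA of N2, protein-coding genes held 3.67% ± 0.626, microRNAs 63.4% ± 1.77 and piRNAs 19.6% ± 1.79. In treated RNA, protein-coding genes held 58.0% ± 4.25 in meg-3 meg-4 and 63.8% ± 1.41 in rde-11. In untreated RNA, microRNAs held 67.4% ± 0.0972 in meg-3 meg-4 and 60.4% ± 0.476 in rde-11, and piRNAs 15.7% ± 0.390 and 22.5% ± 1.15, so that the mutants lay further apart than the spread between replicates. The smallest p that a two-sided exact permutation test can give for 2 libraries against 2 is 0.333, so no p is given for single shares.

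**Figure D1:**
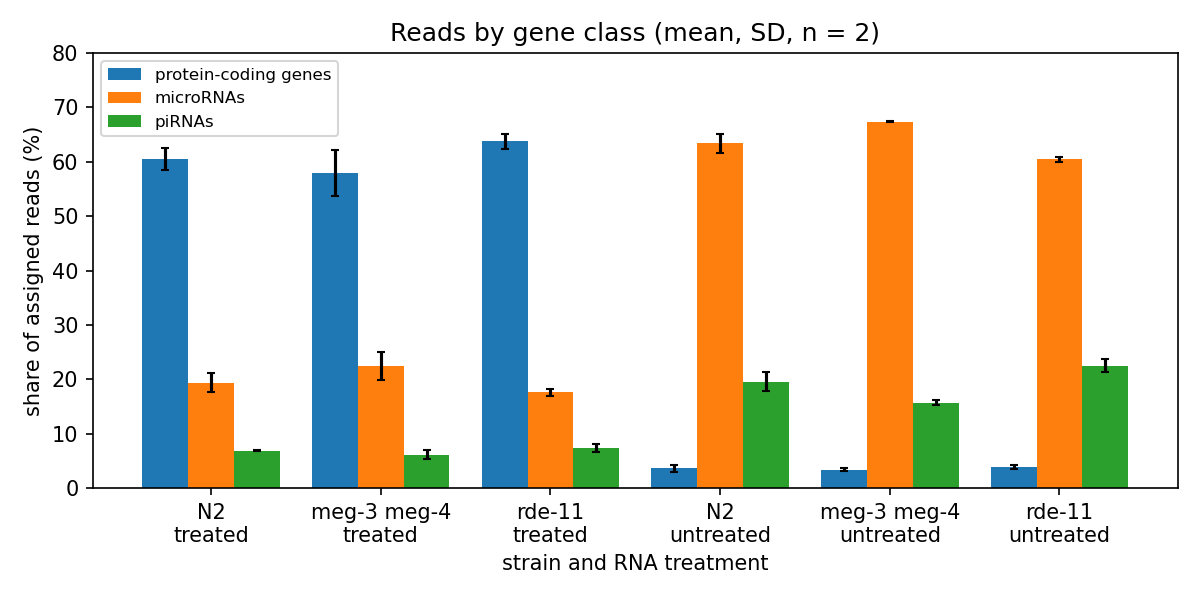
Share of assigned reads (%) held by protein-coding genes, microRNAs and piRNAs in each strain and RNA treatment; bars are means and whiskers SD of 2 libraries. Protein-coding genes held 60.5% of reads in treated and 3.67% in untreated RNA of N2.

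The genes named in the strains' genotypes were examined first, as a check of the labels. Small RNAs of meg-4 stood at 72.0 ± 0.831 fpm (reads scaled to the library total, a CPM unit; mean ± SD, n = 2) in treated RNA of N2, from 356 and 299 reads, and the meg-3 meg-4 libraries held 0 and 2 reads (log2 change -5.96, limma adjusted p = 5.6e-05). Those of meg-3 fell from 12.1 ± 3.21 to 1.19 ± 0.190 fpm (-2.55, limma adjusted p = 0.00153). Both genes are thus nearly without small RNAs in the libraries labelled with their mutation. In rde-11, meg-4 was at 136 ± 0.941 fpm (0.90, limma adjusted p = 0.00127), a call that ended with all 3 strains in 1 fit (adjusted p = 0.0724), and meg-3 at 15.8 ± 3.22 fpm (0.38, limma adjusted p = 0.351). Small RNAs of rde-11 in its own mutant were at 751 ± 10.04 fpm against 633 ± 3.33 fpm in N2 (0.25, limma adjusted p = 0.132). What the hj37 allele changes in the rde-11 gene is not given in the sources used here, so this value checks no label. In untreated RNA, meg-3 and meg-4 were too low to be tested.

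Small RNAs of the fed target pos-1 fell in treated RNA of both mutants and did not pass the test in untreated RNA of either. In treated RNA of N2 they stood at 8292 ± 668 fpm (SD, n = 2), against 2448 ± 464 fpm in meg-3 meg-4, so that N2 held 3.39 times as much. The log2 change was -1.77 with a standard error of 0.12 (limma adjusted p = 2.3e-04). In rde-11 they stood at 1214 ± 138 fpm, with N2 holding 6.83 times as much (log2 change -2.77 ± 0.09 SE, limma adjusted p = 1.7e-09). In untreated RNA, pos-1 stood at 3819 ± 197 fpm in N2, 4419 ± 636 fpm in meg-3 meg-4 and 3392 ± 180 fpm in rde-11, with log2 changes of 0.20 ± 0.11 SE (limma adjusted p = 0.543) and -0.17 ± 0.13 SE (limma adjusted p = 0.650). pos-1 reads of different strands cannot be told apart here, so reads of the fed double-stranded RNA itself are not separated from small RNAs made from the transcript.

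The difference between treatments was itself tested. The change of pos-1 in treated RNA was more negative than in untreated RNA by -1.97 log2 units in meg-3 meg-4 (SE 0.20, adjusted p = 0.00126 for the limma interaction) and by -2.60 in rde-11 (SE 0.15, adjusted p = 3.4e-05). The mutants also differed from each other: pos-1 small RNAs in treated RNA were higher in meg-3 meg-4 than in rde-11 by 1.00 log2 unit (SE 0.13, limma adjusted p = 9.5e-04), and in untreated RNA by 0.38 (SE 0.11, limma adjusted p = 0.0394). The latter call ended with microRNAs centred (0.24, limma adjusted p = 0.113), without a filter on low values (0.217) and without any of 3 of the 4 mutant libraries (0.123 to 0.442). None of the alternative settings run ended or turned a pos-1 call in treated RNA or its interaction, and none brought a call against N2 in untreated RNA.

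**Figure D2:**
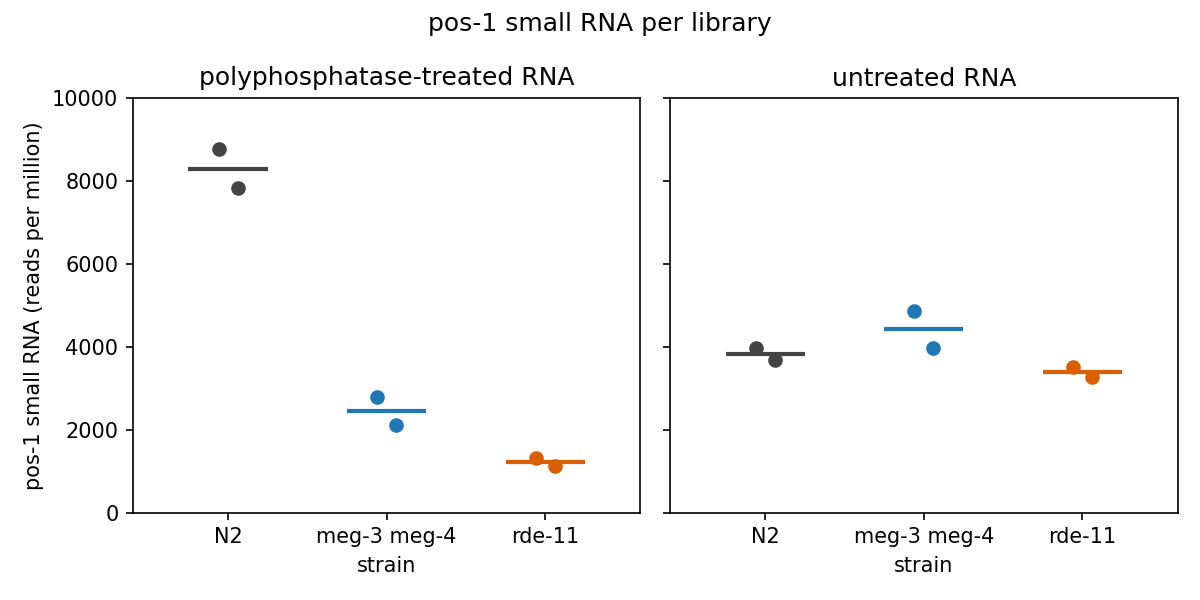
pos-1 small RNAs (fpm, linear axis from 0) in each library, by strain, for treated (left) and untreated RNA (right); points are libraries and lines their means. Means in treated RNA were 8292 in N2, 2448 in meg-3 meg-4 and 1214 in rde-11, and in untreated RNA 3819, 4419 and 3392.

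Other genes of the RNA interference pathway were followed in every comparison. Small RNAs of rde-11 itself rose in treated RNA of meg-3 meg-4, from 633 ± 3.33 to 4359 ± 10.9 fpm, 6.88 times the N2 level (log2 change 2.78 ± 0.08 SE, limma adjusted p = 1.6e-05). They also rose in untreated RNA, from 5.27 ± 0.944 to 18.0 ± 0.923 fpm (1.61 ± 0.28 SE, limma adjusted p = 1.9e-04), a call that ended without a filter on low values (limma adjusted p = 0.682) and without meg-3 meg-4 untreated replicate 1 (0.0576) or 2 (0.0952). Those of sid-1, which encodes the channel that imports double-stranded RNA into cells, rose in meg-3 meg-4 from 648 ± 11.099 to 933 ± 81.9 fpm in treated RNA (0.52 ± 0.12 SE, limma adjusted p = 0.0360). The sid-1 call ended without either N2 treated replicate (adjusted p = 0.347 without replicate 1 and 0.261 without replicate 2) and under other settings, and the authors' deposited table gives it an adjusted p of 0.0545. sid-1 in rde-11 was at 744 ± 44.5 fpm (0.20, limma adjusted p = 0.238). Small RNAs of hrde-1, which encodes a nuclear Argonaute of inherited silencing, and of hrde-2 were not called in any comparison. Their log2 changes in treated RNA of meg-3 meg-4 were -0.02 for each (limma adjusted p = 0.969 and 0.980).

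In treated RNA of meg-3 meg-4, small RNAs against many protein-coding genes fell and those against fewer genes rose. The largest rise at a mean of at least 50 fpm was that of mltn-3, from 1.92 ± 0.992 to 1192 ± 133 fpm (8.71 ± 0.28 SE). Next came F41C3.8 (7.41 to 431 fpm, 5.72), B0564.2 (65.5 to 3146 fpm, 5.57), the F-box gene fbxa-125 (16.08 to 476 fpm, 4.81), B0261.8 (61.04 to 1314 fpm, 4.46), H14A12.5 (15.5 to 284 fpm, 4.10), the thiamine pyrophosphokinase gene tpk-1 (149 to 2304 fpm, 3.94), T05G5.1 (68.6 to 913 fpm, 3.71), Y94H6A.12 (22.4 to 259 fpm, 3.46) and T16H12.2 (143 to 1380 fpm, 3.28). B0564.2 is the next gene to rde-11. The largest falls were those of the pseudogene Y54G2A.42 (166 to 2.17 fpm, -5.73), ndx-2 (397 to 7.47 fpm, -5.56), prx-11, which encodes a peroxisome protein (341 to 6.78 fpm, -5.46), T25D3.3 (115 to 1.87 fpm, -5.36) and ckk-1, a calcium/calmodulin-dependent kinase kinase gene (573 to 16.07 fpm, -5.07). Next were trp-4, which encodes a mechanosensory ion channel (488 to 13.8 fpm, -5.07), gpr-158 (134 to 3.35 fpm, -4.98), cdk-14 (248 to 7.62 fpm, -4.86), kal-1 (123 to 3.51 fpm, -4.79) and rimb-1, which encodes a presynaptic scaffold (160 to 5.49 fpm, -4.62). The highest limma adjusted p among these 20 genes was 1.65e-04, and edgeR called all of them too. Of these, 3 of the 10 that rose and 9 of the 10 that fell overlap another annotated gene, whose reads cannot be told apart without the strand.

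Of 16253 genes tested with limma, 251 were higher and 1093 lower in treated RNA of meg-3 meg-4, of which 165 and 990 changed at least 2-fold. Protein-coding genes made up 206 of the higher and 983 of the lower ones, out of 11011. edgeR on the recovered reads called 315 higher and 909 lower of 13629 genes, and 250 and 909 of them were the same as with limma. The authors' deposited table calls 263 higher and 657 lower. The median change was -0.02 for genes at a level of at least 50 fpm and 0.25 for microRNAs at that level. Higher calls were 18.7% of all calls, and 8.60% with microRNAs centred (121 higher, 1286 lower). Leaving out a library moved the counts widely: without N2 replicate 1 or 2, 142 and 137 genes were higher and 606 and 599 lower, and without meg-3 meg-4 replicate 1 or 2, 989 and 443 were higher and 1767 and 1947 lower.

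Among the gene lists fixed beforehand, calls in treated RNA of meg-3 meg-4 were rare among piRNAs: 1 of 4063 rose and 12 fell (0 and 1 adjusted over the list alone), 0.320% called against 10.9% of other genes (Fisher's exact test, adjusted p = 2.1e-150; camera, adjusted p = 0.922 with an estimated correlation). Single piRNAs have few reads, and changes of low levels are understated. Calls stayed rare at a mean of at least 50 fpm, with 2 of 234 piRNAs called, 0.855% against 22.6% of other genes (Fisher's exact test, adjusted p = 1.4e-20). The list of strain genes (meg-3, meg-4 and rde-11, all 3 called) was the other list called by that test (adjusted p = 0.00621; camera, adjusted p = 0.898 with an estimated correlation), which repeats the label check. Fisher's test treats genes as independent and compares how many members were called, and camera compares their changes. Of microRNAs, 7 of 163 rose and 2 fell (5 and 1 adjusted over the list alone), and this became 2 and 6 when microRNAs were centred on their own median. At a mean of at least 50 fpm Fisher's exact test called this list for few calls, 7.89% against 21.1% of other genes (adjusted p = 0.0331), and camera gave an adjusted p = 0.892 with an estimated correlation. The strain list was then not called (adjusted p = 0.414), with rde-11 alone tested. The microRNAs with the smallest limma adjusted p were mir-257 (72.0 to 12.9 fpm, -2.39), mir-70 (4333 to 6681 fpm, 0.62), mir-8191 (0.952 to 6.52 fpm, 1.99) and mir-246 (4180 to 5455 fpm, 0.39). The microRNA list's median of 0.23 lay above those of all 10000 random lists matched on level, and so did the median of intestine and yolk genes, 0.26 (0.02 with microRNAs centred), with 0 of 16 members called by limma or adjusted over the list alone, 3 at an unadjusted p under 0.05 (all higher) and 0 by edgeR.

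Other lists had few called members in treated RNA of meg-3 meg-4, and Fisher's exact test called none of them. Of 31 histone genes, limma called 0 higher (2 at an unadjusted p under 0.05, 0 by edgeR), and 5 fell (5 adjusted over the list alone): his-61 (85.9 to 14.4 fpm, -2.50), his-16 (-2.65), his-12 and his-43, whose values are identical (-2.63), and his-73 (-1.75), which was named after its values were seen. Of 5 genes whose small RNAs are reported to depend on the Argonautes ERGO-1 and NRDE-3, Y47H10A.5 rose (1814 to 3034 fpm, 0.73), except when microRNAs were centred, and E01G4.5 fell (519 to 137 fpm, -1.91). Of 28 genes of exogenous RNA interference, rde-11 and sid-1 were called. Of 80 ribosomal protein genes, 4 fell (1 adjusted over the list alone): rpl-11.2 (40.5 to 4.26 fpm, -3.01), rps-17 (-1.18), rps-21 (-0.96) and rpl-20. The muscle genes unc-54 (-2.65) and lev-11 (-1.13) fell, 2 of 5, as did the neuronal genes egl-21 (-1.96) and ric-4 (-1.06), 2 of 9. Of 33 sperm genes, spe-41 fell (-1.49) and fer-1 rose (1.47). The Argonaute gene wago-2 rose (0.55), 1 of 23. pal-1, 1 of 37 maternal germline genes, fell (-1.19). So did xol-1, the master switch of sex determination, 1 of 4 genes silenced through piRNAs or HRDE-1 (164 to 69.5 fpm, -1.22). Of these falls, edgeR did not call rps-21 (adjusted p = 0.0722), rpl-20 (0.0638) and ric-4 (0.0594). The authors' deposited table did not call them either (0.306, 0.167 and 0.378), nor rps-17 (0.0832), lev-11 (0.162) and pal-1 (0.23). limma called 0 members of the lists of 21 germ granule genes, 15 genes of inherited silencing, 15 genes of the piRNA pathway, 12 of the 26G pathway, 6 of heat shock, 2 of cuticle and 1 ribosomal RNA. Together with the intestine list these 8 lists had 88 members, of which 8 reached an unadjusted p under 0.05 and edgeR called 1. With camera, 4 lists were called at the preset correlation, all higher: germ granule genes (adjusted p = 0.0370), inherited silencing (0.00418), intestine (0.00109) and microRNAs (5.8e-12). With an estimated correlation, a setting with few degrees of freedom here, camera called none of them (adjusted p = 0.898 each).

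In treated RNA of rde-11, small RNAs against 7 of 28 genes of exogenous RNA interference and 6 of 15 genes of the piRNA pathway rose, and those against 16 of 28 histone genes and 4 of 5 targets of ERGO-1 and NRDE-3 fell. Fisher's exact test called these lists, and camera gave the first and second an adjusted p = 0.644 with an estimated correlation, histones an adjusted p = 0.196 and the targets an adjusted p = 0.203. The largest single rise was that of elt-7, which encodes an intestinal GATA factor, from 2.13 ± 0.704 to 160 ± 9.25 fpm (5.70 ± 0.21 SE). Next were T28D6.4 (22.3 to 290 fpm, 3.63), R13H4.5 (10.1 to 91.6 fpm, 3.04), R102.4 (28.5 to 210 fpm, 2.85), the astacin protease gene nas-36 (91.8 to 423 fpm, 2.24), C07G3.8 (58.4 to 263 fpm, 2.16), cdk-11.2 (76.997 to 242 fpm, 1.63), the potassium channel gene shw-1 (131 to 395 fpm, 1.57), the transporter gene mrp-4 (83.5 to 243 fpm, 1.55) and C27D8.3 (198 to 574 fpm, 1.53). The largest falls were those of the F-box gene fbxa-61 (264 to 1.10 fpm, -6.98), Y110A2AL.1 (863 to 6.46 fpm, -6.86), bbs-5, which encodes a subunit of the ciliary BBSome (329 to 9.96 fpm, -4.92), eri-12 (181 to 6.66 fpm, -4.56) and the ciliary GTPase gene arl-13 (213 to 15.5 fpm, -3.71). Next were ztf-31 (125 to 9.53 fpm, -3.56), Y44E3A.1 (177 to 15.2 fpm, -3.46), R05G6.5 (100.1 to 9.54 fpm, -3.25), the noncoding RNA gene linc-22 (6341 to 733 fpm, -3.11) and ndx-2 (397 to 53.1 fpm, -2.90). The highest limma adjusted p among these 20 was 5.4e-04, for mrp-4, whose call ended with all 3 strains in 1 fit (adjusted p = 0.0543). edgeR called all 20, and 6 of the 10 that rose and 7 of the 10 that fell overlap another annotated gene.

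Of 16491 genes tested with limma, 1045 were higher and 739 lower in treated RNA of rde-11, of which 228 and 424 changed at least 2-fold. Scaling set which direction held more calls. The median change of genes at a level of at least 50 fpm was 0.23, that of microRNAs -0.08. Higher calls were 58.6% of all calls with limma on fpm, scaled to the library total. They were 27.4% with the median gene centred (531 higher, 1406 lower) and 61.9% with microRNAs centred (804 and 495). With edgeR they were 35.6% (611 and 1107 of 13895 genes). limma and edgeR shared 611 higher and 726 lower genes. Of the 1045 higher and 739 lower calls, 531 and 739 were kept with the median gene centred and 793 and 495 with microRNAs centred. The authors' deposited table calls 369 higher and 501 lower. Without rde-11 replicate 2, 323 genes were higher, without N2 replicate 1, 617, and without N2 replicate 2, 1778.

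Histone genes stood out among the fixed lists in rde-11. Of 28 tested in treated RNA, 16 fell and limma called 0 higher (20 fell and 1 rose adjusted over the list alone; 1 higher at an unadjusted p under 0.05, 0 by edgeR), 57.1% called against 10.7% of other genes (Fisher's exact test, adjusted p = 3.1e-08), and 14 to 20 members fell under each other scaling. The examples with the smallest p were his-61 (85.9 to 4.26 fpm, -4.07), his-16 (12.2 to 0.201 fpm, -3.48), and his-12 and his-43, whose values are identical (10.1 to 0.201 fpm, -3.23). The list's median of -1.01 lay below those of all random lists, and camera gave an adjusted p = 1.2e-17 at the preset correlation and an adjusted p = 0.196 with an estimated correlation. At a mean of at least 50 fpm 4 histone genes were tested, and the list was not called (Fisher's exact test, adjusted p = 0.688). Histone genes share near-identical sequences, so reads may be counted for several of them. Of 5 targets of ERGO-1 and NRDE-3, 4 fell under every scaling (4 adjusted over the list alone): E01G4.5 (519 to 102 fpm, -2.32), Y47H10A.5 (1814 to 619 fpm, -1.55), C44B11.6 (1466 to 558 fpm, -1.39) and K02E2.6 (1758 to 865 fpm, -1.02). Fisher's exact test gave the list an adjusted p = 0.00457, and camera gave an adjusted p = 1.3e-10 and an adjusted p = 0.203 with an estimated correlation. At a mean of at least 50 fpm 4 of 4 members were called (Fisher's exact test, adjusted p = 0.0345).

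Among genes of the small RNA pathways themselves, 7 of 28 genes of exogenous RNA interference rose in treated RNA of rde-11 and 1 fell (17 and 1 adjusted over the list alone; Fisher's exact test, adjusted p = 0.0290; camera, adjusted p = 0.644 with an estimated correlation). rrf-1 (147 to 239 fpm, 0.70) and ego-1 (0.75), which encode RNA-dependent RNA polymerases, and the helicase gene drh-1 (0.89) rose, and the Argonaute gene sago-1 fell (5.99 to 0.793 fpm, -1.96). Of 15 piRNA pathway genes, 6 rose (6 adjusted over the list alone; adjusted p = 0.0184; camera, adjusted p = 0.644 with an estimated correlation), among them prg-2 (0.88), snpc-4 (0.83), prde-1 (0.83) and pid-3 (0.69). At a mean of at least 50 fpm neither list was called: 31.6% of the exogenous list against 27.6% of other genes (Fisher's exact test, adjusted p = 0.973) and 55.6% of the piRNA pathway list against 27.5% (adjusted p = 0.567). Of 21 germ granule genes, 6 rose (13 adjusted over the list alone; adjusted p = 0.0567), with wago-1 (73.7 to 167 fpm, 1.16), csr-1 (315 to 563 fpm, 0.86), ifet-1 (0.79) and glh-2 (0.90). Of 15 genes of inherited silencing 4 rose (10 adjusted over the list alone; adjusted p = 0.155), namely wago-1, set-32 (0.64), nrde-4 (0.68) and met-2 (0.63). Of 37 maternal germline genes 7 rose (14 adjusted over the list alone; adjusted p = 0.178), with mex-5 (0.82), cpb-3 (0.55), cbd-1 (0.52) and mex-1 (0.95). With the median gene centred, these rises numbered 5 (and 1 fall), 4, 4, 1 and 2 in the order given. With edgeR they numbered 6 (and 1 fall), 3, 4, 2 and 2. Of the rises named so far, edgeR did not call pid-3 (adjusted p = 0.0518), nrde-4 (0.0587), met-2 (0.0813), cpb-3 (0.0912) and cbd-1 (0.108). The authors' deposited table called none of the 4 maternal genes named (adjusted p = 0.0513 to 0.1495). Nor did it call prde-1 (0.0884), pid-3 (0.112), glh-2 (0.0547), set-32 (0.0816), nrde-4 (0.152) or met-2 (0.105). The Argonaute list (4 of 22 rose and 1 fell) and the 26G list (rrf-3 0.72, dcr-1 0.75 and eri-1 0.73 of 12) were not called by Fisher's exact test. At the preset correlation camera called the exogenous (adjusted p = 3.4e-05), germ granule (4.6e-06), inherited (1.2e-04), piRNA pathway (0.00113) and maternal lists (8.4e-05). With an estimated correlation, which leaves few degrees of freedom here, it called none of them. The adjusted p was then 0.644 for each of the first 4 and 0.714 for maternal genes.

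Some lists held fewer calls than other genes in treated RNA of rde-11. Of 157 microRNAs, 1 rose and 6 fell (1 and 2 adjusted over the list alone; Fisher's exact test, adjusted p = 0.0284; camera, adjusted p = 0.644 with an estimated correlation). mir-262 fell from 490 to 92.4 fpm (-2.39), mir-80 fell by 0.44 and mir-260 by 0.56 on the log2 scale, and mir-253 rose (101 to 205 fpm, 1.02). Of 80 ribosomal protein genes, rpl-6 rose (0.75) and rpl-38 fell (-0.66), 2.50% against 10.9% of other genes (Fisher's exact test, adjusted p = 0.0334). Of 4247 piRNAs, 9 rose and 9 fell (3 and 7 adjusted over the list alone; adjusted p = 3.8e-210). For both lists camera gave an adjusted p = 0.999 with an estimated correlation. At a mean of at least 50 fpm the ribosomal list was not called (Fisher's exact test, adjusted p = 0.688). That test still called piRNAs (0.840% against 29.9% of other genes, adjusted p = 1.5e-30) and microRNAs (8% against 28.1%, adjusted p = 3.1e-04). At a mean of at least 1 fpm the median of microRNAs, -0.08, lay below all random lists and that of piRNAs, 0.11, above all. These medians became -0.28 and -0.10 with the median gene centred. At a mean of at least 50 fpm the piRNA median, 0.12, instead lay at percentile 0.01 of the random lists, whose own median was 0.22. That of microRNAs, -0.08, was at percentile 0.01 there too. Of 16 intestine and yolk genes, the proteases cpr-4 (-1.43) and asp-3 (-1.20) and the yolk gene vit-2 (-0.92) fell (3 adjusted over the list alone; Fisher's exact test, adjusted p = 0.526). This list's median of -0.48 lay below all random lists and was negative under every scaling, and camera gave an adjusted p = 6.6e-05 at the preset correlation and an adjusted p = 0.475 with an estimated correlation. limma called 0 of 33 sperm genes, 0 of 5 muscle genes, 0 of 3 cuticle genes and 0 of 4 genes silenced through piRNAs or HRDE-1. Of these 45 genes, 6 reached an unadjusted p under 0.05 and edgeR called 2. limma called 1 each of 10 neuronal genes (egl-3, 1.37), 6 heat shock genes (hsp-60, 0.74) and the ribosomal RNA rrn-2.1 (-0.52).

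Many genes lost small RNAs in both mutants, and few gained them in both. Of 15841 genes tested in both in treated RNA, 254 were lower in both mutants, where independent lists of 1093 and 739 genes would share 51.0, and 27 were higher in both, where lists of 234 and 1031 would share 15.2. Lower in both were ndx-2 (-5.56 in meg-3 meg-4 and -2.90 in rde-11), T25D3.3 (-5.36 and -1.71), gpr-158 (-4.98 and -1.36) and Y44E3A.1 (-3.78 and -3.46). Higher in both were fbxa-125 (4.81 and 1.45), H14A12.5 (4.10 and 1.53), nas-36 (2.11 and 2.24) and C07G3.8 (1.68 and 2.16). Another 142 genes were called in opposite directions, 110 of them lower in meg-3 meg-4 and higher in rde-11, such as T28D6.4 (-2.04 and 3.63), C27D8.3 (-2.27 and 1.53) and shw-1 (-2.14 and 1.57), and 32 the reverse, such as B0261.8 (4.46 and -1.31).

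Both comparisons use the same N2 libraries, so some overlap arises without any effect. Simulated unchanged mutants against shared controls gave a mean of 0.01 genes in each direction. The simulated lists themselves held means of only 0.19 and 0.21 higher and 0.11 and 0.23 lower genes. The simulation therefore cannot show how far shared controls raise the overlap of long lists. Part of the excess over independent lists may still come from the shared N2 libraries, since 2 libraries cannot be split into sets of 2. Across genes, which are not independent replicates, the changes of the mutants had a Pearson correlation of 0.274 in treated RNA, where the simulation gave 0.499, and a covariance of 0.0893, where it gave 0.0396, a difference of 0.0497. At a level of at least 50 fpm, 108 genes were lower in both (37.0 if independent) and 16 higher (22.2 if independent). Without meg-3 meg-4 treated replicate 1, 353 genes were higher in both, without rde-11 treated replicate 2, 17, and without N2 treated replicate 1, 160 were lower in both.

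**Figure D3:**
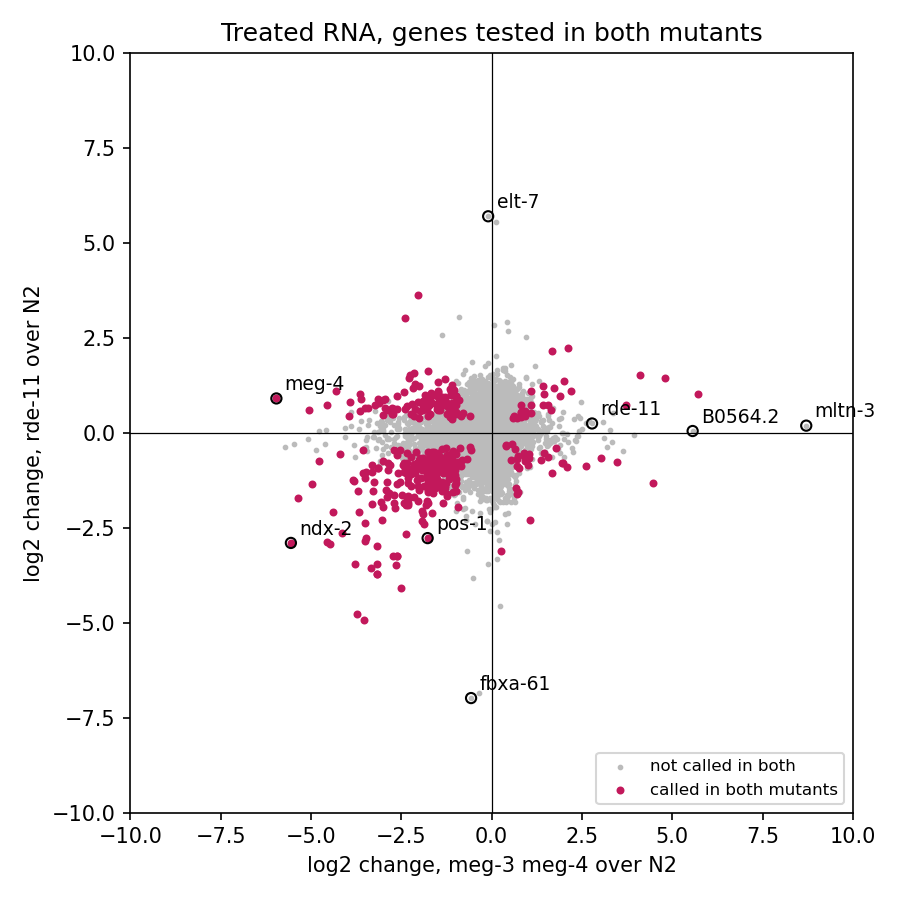
Log2 change against N2 in treated RNA for genes tested in both mutants, meg-3 meg-4 on the x axis and rde-11 on the y axis; each point is a gene, coloured where limma called it in both. pos-1 lies at -1.77 and -2.77, and 254 genes were called lower in both.

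When the mutants were compared with each other directly in treated RNA, limma called 744 of 16340 genes higher and 2051 lower in meg-3 meg-4 than in rde-11. In untreated RNA it called 55 higher and 726 lower of 11281. Scaling set which direction held more calls. In treated RNA, higher calls were 26.6% of all calls with limma on fpm, scaled to the library total. They were 58.2% with the median gene centred (1148 higher, 823 lower), 9.11% with microRNAs centred (406 and 4052) and 55.4% with edgeR (1227 and 988). In untreated RNA they were 7.04%, 91.7% (209 and 19), 2.04% (45 and 2157) and 90.1% (182 and 20).

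In untreated RNA few small RNAs changed in meg-3 meg-4. limma called 13 genes higher and 13 lower of 10902, with 1074 at an unadjusted p under 0.05. At a mean of at least 50 fpm, the microRNAs mir-246 (13553 ± 677 to 18387 ± 264 fpm, 0.44, adjusted p = 0.0262) and mir-70 (14655 ± 358 to 19753 ± 122 fpm, 0.43, adjusted p = 0.0330) rose. T05E12.8 (77.3 to 31.1 fpm, -1.31), the noncoding RNA genes linc-12 (90.7 to 48.0 fpm, -0.89) and linc-154 (231 to 135 fpm, -0.77) and mir-36, a microRNA of the embryonic mir-35 family (3473 to 2383 fpm, -0.53), fell. Of these 6, edgeR called T05E12.8 (adjusted p = 0.0385), and 3 overlap another gene. The authors' deposited table called mir-246 (adjusted p = 0.00114), mir-70 (0.00200) and T05E12.8 (0.0108). It did not call linc-12 (0.764), linc-154 (0.299) or mir-36. With microRNAs centred, mir-246 (0.32, limma adjusted p = 0.0854) and mir-70 (0.31, 0.0963) were not called. With the median gene centred, mir-36, linc-12 and linc-154 were not called. The calls of all 6 ended without meg-3 meg-4 untreated replicate 1 (limma adjusted p = 0.293 for mir-36 to 0.744 for mir-246), all but that of T05E12.8 ended without replicate 2 (0.559 for linc-12 to 0.958 for mir-36), and all 6 ended without a filter on low values (0.682 each). E01G4.5 fell from 16.04 to 5.79 fpm (-1.32), 1 of 4 targets of ERGO-1 and NRDE-3 (Fisher's exact test, adjusted p = 0.0499; camera, adjusted p = 0.795 with an estimated correlation). That list's call rests on this gene, which edgeR (adjusted p = 0.0993) and the authors' deposited table (0.945) do not call. rde-11 was the member called of 18 genes of exogenous RNA interference. Of 166 microRNAs 2 rose and 1 fell (8 and 4 adjusted over the list alone; Fisher's exact test, adjusted p = 0.0488; camera, adjusted p = 0.0855 with an estimated correlation). Of 6146 piRNAs limma called 0 (Fisher's exact test, adjusted p = 8.7e-09; camera, adjusted p = 0.795 with an estimated correlation), with 11 higher and 740 lower at an unadjusted p under 0.05 and 0 by edgeR. With genes of identical reads counted once, Fisher's exact test gave the microRNA and the ERGO-1 and NRDE-3 lists an adjusted p = 0.0691 each, so neither was called. At a mean of at least 50 fpm it gave microRNAs an adjusted p = 0.0752, whereas camera with an estimated correlation did call them at that level. The medians of microRNAs and piRNAs were 0.12, above all random lists, and -0.26, below all random lists, which became 0.37 and -0.01 with the median gene centred and -0.01 and -0.39 with microRNAs centred. The 17 lists without a limma call had 6403 members, piRNAs included, of which 767 reached an unadjusted p under 0.05 and edgeR called 0.

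Scaling set which direction held more calls. The median change of genes at a level of at least 50 fpm was -0.26 and that of microRNAs 0.12. Higher and lower calls were equal in number with limma on fpm, scaled to the library total. Higher calls were 85.2% with the median gene centred (23 higher, 4 lower) and 6.78% with microRNAs centred (12 and 165). With edgeR they were 81.0% (17 and 4 of 7904). Of the 13 higher and 13 lower calls, 12 and 4 were kept with the median gene centred and 11 and 13 with microRNAs centred. The authors' deposited table calls 10 higher and 4 lower. Leaving out N2 untreated replicate 1 or 2 gave 32 and 38 higher and 316 and 45 lower, and leaving out meg-3 meg-4 untreated replicate 1 or 2 gave 7 and 3 higher and 1 and 5 lower. Without a filter on low values limma called 0 genes, with 225 higher and 1121 lower at an unadjusted p under 0.05.

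In untreated RNA of rde-11, a microRNA and some piRNAs rose and a few histone genes fell. mir-253 and F44E7.15, which overlap on opposite strands and have identical values, rose from 301 ± 1.93 to 674 ± 25.01 fpm (1.16, limma adjusted p = 4.9e-10), and mir-253 also rose in treated RNA. The overlapping piRNA genes 21ur-10675, 21ur-15682 and 21ur-4230, again with identical values, rose from 43.2 ± 16.12 to 89.2 ± 5.23 fpm (1.08, limma adjusted p = 1.7e-04). ttbk-8.2, which overlaps the piRNA gene 21ur-8466, fell from 103 to 59.6 fpm (-0.79, limma adjusted p = 0.0211). edgeR with TMM factors called all of these. The calls of the 3 piRNA genes ended with edgeR's RLE factors (adjusted p = 0.0569), with DESeq2 (0.0799), in the authors' deposited table (0.0716), without a filter on low values (limma adjusted p = 0.634) and with each library left out in turn (limma adjusted p = 0.0808 to 0.865 for 21ur-10675, log2 change 0.70 to 1.46). That of ttbk-8.2 also ended without a filter (0.746) and with each library left out in turn (limma adjusted p = 0.312 to 0.865), and that of mir-253 without N2 untreated replicate 1 (0.0963) or 2 (0.0582). limma called 46 genes higher and 23 lower of 11629, with 1291 at an unadjusted p under 0.05. The germ granule gene pgl-3 fell (7.75 to 0.730 fpm, -2.33), as did Y47H10A.5 (22.1 to 4.92 fpm, -1.95) and mir-788 (-0.87), while hsp-60 (1.18) and the yolk gene vit-6 (0.95) rose with limma. Neither rise was called by edgeR (adjusted p = 0.291 and 0.384) or in the authors' deposited table (0.990 and 0.9998). Of 13 histone genes 4 fell (4 adjusted over the list alone; Fisher's exact test, adjusted p = 8.2e-06), which were his-61 (-1.63) and the identical his-12, his-16 and his-43, at 2.47 fpm in N2 and 0 reads in the mutant, which allows up to 3 reads per library. Counting the identical genes once gave 2 of 11 (Fisher's exact test, adjusted p = 0.0250), and camera gave an adjusted p = 5.7e-06 at the preset correlation and an adjusted p = 0.481 with an estimated correlation. edgeR called 1 histone gene lower, and the list's median stood at percentile 7.91 of the random lists. Of 6506 piRNAs, 11 rose and limma called 0 lower (7 and 0 adjusted over the list alone; Fisher's exact test, adjusted p = 1.7e-10; camera, adjusted p = 0.656 with an estimated correlation), with 532 higher and 28 lower at an unadjusted p under 0.05. These calls became 5 higher and 2 lower with the median gene centred and 3 and 2 with edgeR. The medians of inherited silencing genes (0.68), germ granule genes (0.58), ribosomal protein genes (0.41) and piRNAs (0.19) lay above all random lists and that of microRNAs (-0.01) below. With the median gene centred they were 0.53, 0.43, 0.25, 0.04 and -0.16, and camera gave microRNAs an adjusted p = 0.481 and the other 4 lists an adjusted p = 0.656 with an estimated correlation. The 14 lists without a limma call had 246 members, of which 56 reached an unadjusted p under 0.05 and edgeR called 0.

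The median change of genes at a level of at least 50 fpm in untreated RNA of rde-11 was 0.16 and that of microRNAs -0.01. Higher calls were 66.7% with limma on fpm, scaled to the library total. They were 40.4% with the median gene centred (21 higher, 31 lower) and 64.5% with microRNAs centred (40 and 22). With edgeR they were 31.4% (11 and 24 of 8405). The authors' deposited table calls 7 higher and 12 lower. Without N2 untreated replicate 1, limma called 0 genes in either direction (388 higher and 222 lower at an unadjusted p under 0.05), and without replicate 2 it called 1 higher and 0 lower (1333 and 74 at an unadjusted p under 0.05). Without rde-11 untreated replicate 1 or 2, 19 and 4 genes were higher and 9 and 7 lower. In untreated RNA, limma and edgeR each called 2 genes higher and 0 lower in both mutants (29 and 34 with limma and 31 and 33 with edgeR at an unadjusted p under 0.05), and 3 were called in opposite directions among 10651. Those higher in both were K07F5.6 (3.28 in meg-3 meg-4 and 3.43 in rde-11) and srbc-60 (1.58 and 1.73), and those lower in meg-3 meg-4 and higher in rde-11 were Y57G11C.51, M163.14 and linc-154. Apart from linc-154, these were named after their values were seen. The covariance of the changes was 0.0479, where shared controls alone gave 0.0548.

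limma's interaction called 81 genes more positive and 476 more negative in treated RNA of 16459 in meg-3 meg-4, and 16 and 61 of 16916 in rde-11. edgeR called 5 and 13 for meg-3 meg-4 and 3 and 21 for rde-11, and pos-1 was among those called by both tools for each mutant. Leaving out any 1 library gave limma counts of 32 to 45 and 187 to 351 for meg-3 meg-4 and 2 to 13 and 7 to 42 for rde-11. With levels of at least 50 fpm in both treatments, limma called 4 genes more positive and 1 more negative of 367 for meg-3 meg-4: rpr-1, T08B6.64, T26A8.6 and Y74C9A.6, and pos-1. For rde-11 it called 0 more positive (0 at an unadjusted p under 0.05) and 4 more negative of 374: pos-1, T05E12.10, Y116A8B.1 and Y57G11C.51. Apart from pos-1, these genes were chosen after their values were seen. Of the genes named above with an interaction call, 20 of 22 in meg-3 meg-4 and 13 of 14 in rde-11 had a mean under 10 fpm in untreated RNA, where changes are understated. Some of them were under 1 fpm there, too low for a test of their change in untreated RNA. The edgeR estimate had the opposite sign for B0261.8, Y94H6A.12, prx-11 and rimb-1 in meg-3 meg-4 and for T28D6.4 and R13H4.5 in rde-11.

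**Figure D4:**
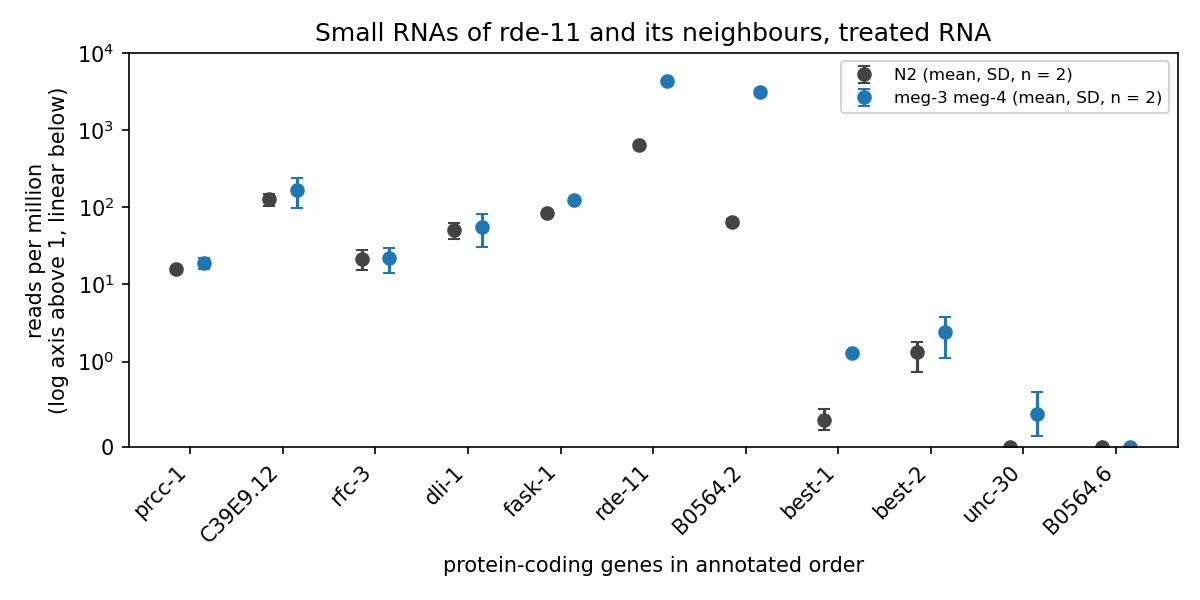
Small RNAs (fpm, log axis above 1 and linear below) of rde-11 and the protein-coding genes next to it in treated RNA of N2 and meg-3 meg-4; points are means and whiskers SD of 2 libraries. rde-11 (633 to 4359) and its neighbour B0564.2 (65.5 to 3146) rose, and fask-1 on the other side (83.9 to 125), shown after its values were seen, was not called.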

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

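An interaction between RNA treatment and genotype was planned. Its limma fit replaced the foreseen calculation once the columns were known, and the edgeR interaction was a test chosen only after the result was seen. The values here are the log2 change against N2 in treated RNA minus that in untreated RNA, for the genes named in the report whose difference passed the limma interaction test.

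In meg-3 meg-4, 22 named genes passed the limma interaction test. The fed target pos-1 was more negative in treated RNA by -1.97 log2 units, and rde-11 was more positive by 1.18. The other positive differences were 6.84 for mltn-3, 5.06 for F41C3.8, 4.06 for fbxa-125, 3.45 for H14A12.5, 2.82 for Y94H6A.12, 2.56 for B0564.2, 2.28 for B0261.8, 2.21 for T05G5.1 and 2.04 for tpk-1. The negative differences were -5.81 for meg-4, -5.53 for T25D3.3, -4.98 for Y54G2A.42, -4.96 for ndx-2, -4.82 for gpr-158, -4.65 for kal-1, -4.24 for prx-11, -4.05 for cdk-14, -3.94 for rimb-1, -3.83 for trp-4 and -3.17 for ckk-1. The edgeR interaction also called 4 of the 22: pos-1, T25D3.3, ndx-2 and gpr-158. Its estimate had the opposite sign, without a call, for B0261.8 (-3.01), Y94H6A.12 (-1.35), prx-11 (0.64) and rimb-1 (0.43), and was 0.47 for B0564.2.

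In rde-11, 14 named genes passed the limma interaction test. pos-1 was more negative in treated RNA by -2.60 log2 units. The other negative differences were -6.18 for fbxa-61, -5.13 for Y110A2AL.1, -4.74 for bbs-5, -3.95 for eri-12, -3.35 for Y44E3A.1, -3.24 for arl-13, -3.14 for R05G6.5, -3.01 for ztf-31 and -2.16 for ndx-2. The positive differences were 5.14 for elt-7, 2.85 for R102.4, 2.79 for R13H4.5 and 2.59 for T28D6.4. The edgeR interaction also called 4 of the 14: pos-1, bbs-5, arl-13 and ztf-31. Its estimate had the opposite sign, without a call, for T28D6.4 (-2.16) and R13H4.5 (-0.59).

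Level limits what these differences show. The mean in untreated RNA was under 10 fpm for 20 of the 22 genes in meg-3 meg-4 and for 13 of the 14 in rde-11, where the added 1 fpm understates changes. Some were under 1 fpm there and had no tested change in untreated RNA. Examples are meg-4 (0.0548 fpm) and rimb-1 (0.331 fpm) in meg-3 meg-4, and R13H4.5 (0.108 fpm) and elt-7 (0.236 fpm) in rde-11. The differences of such genes rest mainly on the treated change. Most of these genes were named for large changes in treated RNA, so the size of their differences is set in part by that choice. Besides pos-1, the genes called by both tools had under 10 fpm in untreated RNA, so their differences are less certain. The edgeR interaction did not call rde-11 in meg-3 meg-4 (1.05, adjusted p = 0.9999). For genes called by limma alone, these values do not show that they respond differently in the RNA treatments. The untreated change was still large for some of them, such as 3.01 for B0564.2, 2.18 for B0261.8, 1.91 for tpk-1, 1.87 for mltn-3 and -1.91 for ckk-1 in meg-3 meg-4, and -1.73 for Y110A2AL.1 in rde-11. pos-1 is far above this level, with 3819 fpm in untreated RNA of N2, 4419 fpm in meg-3 meg-4 and 3392 fpm in rde-11.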

How the results depend on the processing

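Fixed beforehand were the DESeq2 and RLE settings, the filters, the block, the fit of 3 strains, the pseudocounts, the thresholds, both centrings, the camera test with an estimated correlation and each library left out. The edgeR TMM fits, the deposited table, camera at its preset correlation, the list test with genes of identical reads counted once, and the alternatives carried over to the overlap, the interaction, the list tests and the comparison of the mutants with each other were tests chosen only after the result was seen. Counts are given as higher then lower in the mutant, list counts are lists called by Fisher's exact test, and T and U stand for treated and untreated RNA. Of 562 alternative values of the main counts and of pos-1, 317 kept their direction and side of the threshold or stayed within 1.5 times, 240 counts moved, and 5 values of pos-1, all between the mutants in U, lost their call. Against N2 all values of pos-1 were kept: over 18 settings its change ran from -2.02 to -1.54 in meg-3 meg-4 T (highest adjusted p = 0.00228, over the limma, edgeR and DESeq2 fits), from -2.98 to -2.66 in rde-11 T (1.7e-04), from 0.06 to 0.46 in meg-3 meg-4 U (lowest adjusted p = 0.0755) and from -0.40 to -0.12 in rde-11 U (0.379). Over 16 settings its interaction ran from -2.17 to -1.78 in meg-3 meg-4 (highest adjusted p = 0.0226 over the limma and edgeR fits) and from -2.77 to -2.49 in rde-11 (0.00643).

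The counts of reference are these. meg-3 meg-4 T had 251 higher and 1093 lower, rde-11 T 1045 and 739, meg-3 meg-4 U 13 and 13, and rde-11 U 46 and 23. Shared calls were 27 and 254 in T and 2 and 0 in U, interaction calls 81 positive and 476 negative in meg-3 meg-4 and 16 and 61 in rde-11, and lists called 2, 7, 4 and 2 in the order of the comparisons. Values that moved are given by setting.

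With DESeq2, lower counts were 659 (meg-3 meg-4 T), 4 (meg-3 meg-4 U) and 12 (rde-11 U), and higher counts 364 (rde-11 T), 7 (rde-11 U), 13 (shared T) and 0 (shared U), while lists were 4 (meg-3 meg-4 T) and 2 (meg-3 meg-4 U). The authors' deposited table gave 657, 4 and 12 lower, 369, 7, 13 and 1 higher in the same order, and 2 lists (meg-3 meg-4 U). edgeR with RLE factors gave 380 higher (meg-3 meg-4 T), 593 higher (rde-11 T), 4 lower (meg-3 meg-4 U), 8 higher (rde-11 U) and 3 and 1 lists in rde-11 T and U. edgeR with TMM gave 611 higher (rde-11 T), 4 lower (meg-3 meg-4 U), 11 higher (rde-11 U) and 3 and 1 lists in rde-11 T and U. For these tools the cause was not tested.

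Without a filter on low values, counts were 157 and 299 in rde-11 T, 0 and 0 in meg-3 meg-4 U (225 and 1121 at an unadjusted p under 0.05 in limma), 4 and 4 in rde-11 U, 7 and 135 shared T and 0 higher shared U. Interaction counts were 52 and 309 in meg-3 meg-4 and 4 and 12 in rde-11, and lists 3 (rde-11 T), 0 (meg-3 meg-4 U) and 1 (rde-11 U). More genes are tested there. At a mean of at least 10 fpm, fewer are: 477 lower (rde-11 T), 2 higher (meg-3 meg-4 U), 13 lower (rde-11 U), 1 higher (shared U), and 1 list each in meg-3 meg-4 T and rde-11 U. At a mean of at least 50 fpm, shared counts were 16 and 108 in T and 0 higher in U, interaction counts 4 and 1 in meg-3 meg-4 and 0 and 4 in rde-11, and lists 3 (rde-11 T), 1 (meg-3 meg-4 U) and 1 (rde-11 U). With a pseudocount of 0.5, interaction counts were 40 and 234 in meg-3 meg-4 and 6 and 15 in rde-11, and with 5 they were 207 and 1082, and 123 and 313. The edgeR interaction gave 5 and 13, and 3 and 21. The cause was not tested.

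With microRNAs centred, 121 genes were higher in meg-3 meg-4 T and 165 lower in meg-3 meg-4 U, 15 shared higher in T, 4 shared lower in U, and 2 lists called in meg-3 meg-4 U. With the median gene centred, counts were 531 and 1406 in rde-11 T, 23 and 4 in meg-3 meg-4 U and 21 higher in rde-11 U, 416 were shared lower in T, and 4 lists called in rde-11 T. Centring moves every gene of a library by the same amount. With all 3 strains in 1 fit, counts were 149 and 379 in rde-11 T and 19 and 13 in rde-11 U, 17 and 156 shared in T, and lists 3 (rde-11 T), 2 (meg-3 meg-4 U) and 1 (rde-11 U); that fit pools the spread of the strains, and the cause was not tested.

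At an adjusted p under 0.01, a stricter rule, limma gave 141 and 598 (meg-3 meg-4 T), 284 and 381 (rde-11 T), 24 and 13 (rde-11 U) and 11 and 135 (shared T), with 3 lists in rde-11 T and 2 in meg-3 meg-4 U. At a change of at least 2-fold, counts were 165 higher (meg-3 meg-4 T), 228 and 424 (rde-11 T) and 11 and 135 (shared T), again with 3 and 2 lists. camera at the preset correlation called 4 lists in meg-3 meg-4 T and 9 in each mutant in U, and with an estimated correlation 0 in all comparisons at a mean of at least 1 fpm. At a mean of at least 50 fpm, camera with an estimated correlation called microRNAs in meg-3 meg-4 U (adjusted p = 0.004745). With genes of identical reads counted once, Fisher's exact test called 2 lists in meg-3 meg-4 U.

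With the replicate number as a block, counts were 541 and 2048 (meg-3 meg-4 T), 2909 and 1304 (rde-11 T), 30 and 42 (meg-3 meg-4 U), 87 higher (rde-11 U), 139 and 578 (shared T) and 4 lower (shared U), with 130 positive interactions in meg-3 meg-4 and 12 lists in rde-11 T. All calls made without the block were kept except 1 of the 46 higher in rde-11 U. Same-numbered libraries deviated together, with correlations across 7101 genes of 0.169 to 0.594 over 15 pairs of groups, but there are only 2 numbers and the labels do not say that a number marks a shared batch, so pairing was not assumed.

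Leaving out 1 library leaves an arm with a single sample, assumed to vary like the others. Lowest and highest counts were 137 to 989 higher and 599 to 1947 lower (meg-3 meg-4 T), 323 to 1778 and 496 to 730 (rde-11 T), 3 to 38 and 1 to 316 (meg-3 meg-4 U), 0 to 19 and 0 to 9 (rde-11 U), 17 to 353 and 160 to 320 (shared T), and 0 to 2 and 0 to 0 (shared U). Interaction counts were 32 to 45 positive and 187 to 351 negative in meg-3 meg-4 and 2 to 13 and 7 to 42 in rde-11. Lists called were 2 to 5, 3 to 12, 1 to 4 and 0 to 1. The highest counts in meg-3 meg-4 T came without its own replicate 1 (higher) or 2 (lower), and in meg-3 meg-4 U without N2 replicate 2 (higher) or 1 (lower).

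Between the mutants, limma gave 744 higher and 2051 lower in meg-3 meg-4 than in rde-11 in T and 55 and 726 in U. With edgeR these were 1227 and 988 in T and 182 and 20 in U, with the median gene centred 1148 and 823, and 209 and 19, and with microRNAs centred 406 and 4052, and 2157 lower in U. Without a filter on low values, 1359 were lower in T, and 7 and 10 were called in U. With the block there were 1124 and 4034, and 134 and 1916. With single libraries left out there were 314 to 973 and 680 to 4313 in T and 20 to 88 and 84 to 1135 in U. pos-1 was higher in meg-3 meg-4 in T by 0.67 to 1.35 (highest adjusted p = 0.0150 over the limma and edgeR fits). In U its call ended without a filter (0.38, limma adjusted p = 0.217), with microRNAs centred (0.24, 0.113) and without meg-3 meg-4 replicate 1 (0.23, 0.442) or either rde-11 replicate (0.123 and 0.186), and its lowest and highest changes with a library left out were 0.23 and 0.52.

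Of the values of single named genes in treated RNA, 921 of 935 kept their side of the threshold, 12 lost their call (sid-1 in meg-3 meg-4 under 9 settings, meg-4 in rde-11 under 2, mrp-4 under 1) and 2 gained one under the block (rde-11 and sid-1 in rde-11). In untreated RNA, 261 of 350 did, and 89 lost their call. No called value turned direction. The uncalled changes of hrde-1 and hrde-2, and of sid-1 in rde-11 T, changed sign under some settings, with hrde-2 in rde-11 U between -1.07 and 0.66 as single libraries were left out. Not run were the adjustments recomputed from the authors' unadjusted p-values, since no such column was used. Protein-coding genes held 3.67% of reads in untreated RNA of N2, and genes such as meg-3 and meg-4 were too low there to be tested.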

Other observations

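Among the tests reported here, those of genes overlapping rde-11, of the scaling of rde-11, of neighbouring pairs in meg-3 meg-4, of less RDE-11 activity and of F-box genes were tests chosen only after the result was seen. The count of neighbouring pairs was prompted by the neighbours rde-11 and B0564.2, and mltn-3 and mltn-5. Genes named below that the report does not name were chosen after their values were seen.

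Of 190 tested fbxa, fbxb and fbxc genes, F-box genes that encode substrate adaptors of ubiquitin ligases, limma called 53 lower and 5 higher in treated RNA of meg-3 meg-4, 27.9% lower against 8.59% of other protein-coding genes. Examples of the lower ones were fbxa-184 (-3.90), fbxa-216 (-3.16), fbxa-170 (-2.88), which lies next to the mutated meg-4, and fbxa-120 (-1.86). edgeR called 44 lower. In rde-11, 26 of 193 were lower, 13.5% against 5.57%.

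Whether the F-box result is a property of the group was tested with 10000 draws of genes matched on level. The draws gave a median of 16 lower genes and at most 32, against the 53 observed, a share of 1e-04, which is the smallest they can give. The family was picked from a scan of name families, for which this share is not corrected. The same reads counted for several F-box genes would leave identical values, and 0% of the lower F-box genes had values identical to another gene. Reads shared in part between paralogs could still move several members together, so a loss of small RNAs by the F-box group as a whole remains a hypothesis.

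Small RNAs of rde-11 rose in meg-3 meg-4, and several technical explanations were set against it. Reads shared with an overlapping gene would need such a gene, and 0 annotated genes overlap rde-11 in WBcel235. Scaling to the library total does not account for the rise, since the lowest log2 change under both centrings was 2.54. Whether the change is spread over neighbouring genes stays open: 9 neighbouring pairs of genes were higher together in meg-3 meg-4 (share of level-matched draws 0.0166), but without the prompting pairs 7 were, against a median of 4 and at most 11 in the draws (share 0.093). The strain's background next to rde-11 was not tested and stays open.

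The other pairs higher in meg-3 meg-4 were mltn-3 and mltn-5, T23G11.11 and T23G11.1, Y94H6A.12 and Y94H6A.7, bath-15 and mab-5, pmk-1 and faah-2, mdt-21 and C24H11.5, B0284.3 and pals-27, and fbxc-43 and fbxc-44. In treated RNA of rde-11, C18G1.9 (5.56), which lies beside elt-7 (5.70), and C18G1.8 (3.06), the next gene beyond it, rose with it. Over all genes higher in rde-11 there were 92 neighbouring pairs, against a median of 90 and at most 123 in the draws (share 0.423), so changes shared by neighbouring genes were not told apart from level-matched chance there.

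Genes lower in both mutants in treated RNA exceeded the number for independent lists. Noise private to single N2 libraries as the whole cause would leave nothing once each mutant has its own N2 library. The median change in meg-3 meg-4 of genes lower in rde-11 was then -0.48 and -0.43 for the possible assignments. These lay below the lowest draws of -0.24 and -0.17. A deviation common to both N2 libraries would stay in either assignment, so this test cannot exclude it. Counting genes with identical values once left 253 lower in both, against 54.7 if independent. Less RDE-11 activity in meg-3 meg-4 stays open, since genes higher in rde-11 had medians of -0.09 and 0.048 in meg-3 meg-4, above the highest draws of -0.15 and 0.02, whereas, with the shared N2 libraries, 110 of 1031 genes higher in rde-11 were called lower in meg-3 meg-4, more than the 71.1 of independent lists. At a level of at least 50 fpm, 16 were higher in both mutants and 51 opposite in this way, against 22.2 and 66.1 of independent lists. A background shared by the mutant strains was not tested and stays open.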
